A study of Mus musculus with 9 samples.

How the data were processed

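RNA was measured on Affymetrix whole-transcript arrays in 9 mouse samples of 3 groups with 3 arrays each: embryonic fibroblasts at a passage below 3 (MEF), the embryonic stem cell line R1, and induced pluripotent stem cells (iPS cells), which are somatic cells returned to a state like that of embryonic stem cells. Per the labels, the MEF are the cells from which the iPS cells were made, total RNA was extracted with Trizol, and biotin-labelled cDNA was made with the manufacturer's whole-transcript kits. The design text describes the arrays of a line as biological repeats. It does not say whether they came from separate derivations, so p-values measure the spread between these cultures.

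The deposited values are linear intensity values, 1 per probe set and array, and the submitters' processing notes name GCOS 1.4 without a role. Background correction, summarization, normalization and the array design are not given in the sources used here. The values lay between 4 and 18820.3, and each was a power of 2 of a number with 2 decimals, with a largest departure of 7e-10. Array medians ranged from 6.29 to 6.38 on the log2 scale, a range of 0.09, so no further normalization was applied. No pair of arrays held identical values. No detection calls were used, so a low signal is not told apart from background. The median signal per array was 78.2 to 83.3, and 30.1% of genes had a mean signal under 50. Precision was limited by the 3 arrays per group.

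Of 35557 probe sets, 21789 had 1 gene symbol in the platform annotation, 1621 had several and 12147 were not listed there. The latter 2 kinds are unnamed here and were left out of the main comparisons. Entrez identifiers were looked up in a RefSeq gene table of assembly GRCm38.p6, which held 21698 of the 21789 named probe sets and changed 0 symbols. That table served only for names and for which genes neighbour each other, so no coordinates are given. For the 999 genes with several probe sets, the probe set with the highest mean over all arrays was used, which left 19938 genes. Among 133 genes named by rule, 5 had several probe sets, and in no comparison did another probe set move the opposite way by 0.5 or more. The second probe set of Dab2 showed almost no change (0.03 in iPS against MEF).

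Signals were analysed as log2(signal + 16), so differences of dim genes are understated. The comparisons were iPS against MEF, R1 against MEF and iPS against R1. All arrays entered 1 fit with a mean per group in limma 3.58.1 (lmFit and eBayes, R 4.3.3), with 6 residual degrees of freedom, and p-values were adjusted by Benjamini-Hochberg over all genes. A gene was called at an adjusted p under 0.05 and an absolute log2 difference of 1 or more. "Rose" and "fell" are used of called genes and, for gene lists, of a list whose test passed. Differences are given with the standard error of the fit and signals as mean and SD of 3 arrays. All adjusted p-values of genes are limma's.

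The 26 gene lists held 598 genes, of which 544 were measured, with 6 in more than 1 list, and were fixed before the data were examined. They cover reprogramming factors, the pluripotency network, fibroblast and matrix genes, mesenchymal regulators, epithelial genes, imprinted genes, germ layers, trophoblast, germline, the 2-cell stage, Hox clusters, cell cycle, chromatin, signalling, metabolism, housekeeping, sex-linked genes and cell types that such cultures could hold. Each list was tested against the other genes with camera at its preset inter-gene correlation of 0.01, adjusted over 78 list tests. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance one way without comparing them with other genes, were alternatives. The rule for named genes was also fixed before the data were examined. For each comparison it took the 8 largest increases and the 8 largest decreases among called genes with fully separated arrays, passing over predicted and Riken symbols, and up to 4 called members of each list. It added, called or not, the 4 reprogramming factors, Nanog, Zfp42, Cdh1, Thy1, Col1a1, the Dlk1-Dio3 imprinted cluster and the sex-linked genes. Genes named outside this rule are said to be so.

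Both comparisons against MEF share the MEF arrays, so unchanged groups were simulated against the same arrays 100 times to obtain the correlation of fold changes without effects. Shares are given with exact binomial 95% intervals, which treat genes as independent and do not measure the spread between arrays. Alternatives covered normalization, the filter on dim genes, the treatment of several probe sets, thresholds, the pseudocount, array weights, an intensity trend, the replicate number as a block, and leaving out each array in turn. The scripts were tested on simulated data made from the real means and spreads of 19938 genes with 200 changed genes. In the simulation of iPS against R1, 98% of 50 genes changed by 1.25 log2 units and 100% of 50 genes changed by 2 were called, with 0 false calls.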

Results

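The expression of 19938 genes was compared between mouse embryonic fibroblasts (MEF), iPS cells derived from them, and the embryonic stem cell line R1, with 3 arrays per group. According to the design text, embryonic stem cells and fibroblasts were the controls of the iPS cells. Median signals of the 9 arrays lay between 78.2 and 83.3.

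The R1 and iPS arrays resembled each other far more than either resembled the fibroblasts. Across genes, which are not independent replicates, the mean Pearson correlation between R1 and iPS arrays was 0.991 ± 0.0013 (SD of 9 pairs of arrays). It was 0.895 ± 0.0048 between MEF and R1 arrays and 0.905 ± 0.0033 between MEF and iPS arrays. Within a group, mean correlations were 0.9966 for MEF, 0.9965 for R1 and 0.9961 for iPS. The first principal component held 90.6% of the variance and separated MEF (-75.3 to -70.3) from R1 (36.6 to 41.2) and iPS (30.8 to 34.8). The second component, with 4.34% of the variance, separated R1 (-13.7 to -12.8) from iPS (12.5 to 17). When dim genes were left out, the correlations were 0.820 for MEF with R1, 0.836 for MEF with iPS and 0.985 for R1 with iPS.

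The comparison of iPS cells with MEF asks how the derived cells differ from their cells of origin. Genes of the pluripotency network rose and genes of fibroblasts and their extracellular matrix fell, calls that both lists lost with an estimated correlation (adjusted p = 0.229 and adjusted p = 0.260). The signal of Pou5f1, the transcription factor Oct4, rose from 53.05 ± 9.9 in MEF to 4137 ± 180 in iPS arrays (SD, n = 3), a log2 difference of 5.92 ± 0.09 (SE). Sox2 rose by 5.27 ± 0.07, and Nanog, a homeobox factor of the same network, by 5.82 ± 0.09. Col1a1, which encodes a chain of type I collagen, fell from 10144 ± 597 to 1229 ± 108, a log2 difference of -3.03 ± 0.15. In all, 2523 genes were called, of which 1013 were higher and 1510 lower in iPS cells, and the arrays of both groups were fully separated for all 2523. Chance gives such separation of 3 against 3 arrays for 10% of unselected genes. The thresholds of a call favour it, so it adds no support.

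Of 45 measured genes of the pluripotency network, 42 rose and 0 fell. The largest increases were those of Dppa5a (6.94 ± 0.24), Tdgf1, a co-receptor of Nodal (6.65 ± 0.12), and Nr0b1 (6.50 ± 0.20). Stat3, which transmits the LIF signal, had a log2 difference of -0.71, Foxd3 of 0.91 and Fut4 of -0.11, and these 3, named outside the rule, were not called. The list rose as a whole (camera adjusted p = 3.58e-22; adjusted p = 0.229 with an estimated correlation). Of the reprogramming factors, Klf4 rose (1.76 ± 0.06) while Myc, which MEF expressed at a signal of 1520 ± 116, fell (-1.19 ± 0.12). The 4 factors rose as a list (adjusted p = 0.0233; adjusted p = 0.293 with an estimated correlation). For this and every other list, the number of called genes adjusted over the list alone was the same as over all genes tested. No list test of the 78 passed with an estimated correlation, where the lowest adjusted p was 0.229, and 36 passed with the preset one. Fry called 46, among them in iPS against MEF the pluripotency list (fry adjusted p = 2.81e-08) and the fibroblast list (fry adjusted p = 2.21e-06). Of the 36, 3 lost their call under fry. Fry does not compare a list with other genes, so it asks a different question.

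Among 37 fibroblast and matrix genes, 34 fell and 1 rose (camera adjusted p = 2.94e-17; adjusted p = 0.260 with an estimated correlation). Fbln5, an elastic-fibre protein, fell (-4.57 ± 0.10), as did periostin (Postn, -3.98 ± 0.26) and Col12a1 (-3.94 ± 0.15). The gene that rose was Mmp3, a matrix metalloproteinase (2.90 ± 0.11), and the decorin gene Dcn differed by 0.40 ± 0.14 without being called; neither was named by rule. Thy1, a surface marker of fibroblasts, fell by 2.88. Of 24 mesenchymal regulators 22 fell (adjusted p = 2.50e-15; adjusted p = 0.247 with an estimated correlation), among them Tgfb3 (-4.15 ± 0.17), Prrx1 (-3.07 ± 0.12) and the cadherin Cdh11 (-3.07 ± 0.14). Of 24 epithelial genes 15 rose and 1, Krt19 (-1.44 ± 0.12; named outside the rule), fell (adjusted p = 9.29e-09; adjusted p = 0.255 with an estimated correlation). Epcam rose by 5.08 ± 0.09, E-cadherin (Cdh1) by 4.43 ± 0.09 and the splicing regulator Esrp1 by 4.40 ± 0.12.

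The other genes among the largest increases were Trh (5.98 ± 0.14), the DNA methylation cofactor Dnmt3l (5.44 ± 0.15) and Fam169a (5.36 ± 0.07). Among the largest decreases were also Lrrc17 (-4.36 ± 0.17), the semaphorin receptor Nrp1 (-4.30 ± 0.19), Aspn (-4.26 ± 0.15), pleiotrophin (Ptn, -4.18 ± 0.11), Pcdh18 (-4.09 ± 0.14) and Fbn2 (-4.08 ± 0.13).

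Germline and meiosis genes rose, with 9 of 24 called (adjusted p = 2.47e-06; adjusted p = 0.255 with an estimated correlation), for example Ddx4 (2.91 ± 0.19) and Tex19.1 (2.52 ± 0.11). Of 19 glycolysis genes 9 rose (adjusted p = 7.69e-07; adjusted p = 0.293 with an estimated correlation), led by the glucose transporter Slc2a3 (4.60 ± 0.09) and Pdk1 (3.11 ± 0.14). Chromatin and DNA methylation genes rose, with 11 of 33 called higher and 2 lower (adjusted p = 2.11e-06; adjusted p = 0.247 with an estimated correlation). These included the methylcytosine dioxygenase Tet2 (2.54 ± 0.11) and the Polycomb proteins Cbx7 (2.50 ± 0.11) and Mtf2 (2.31 ± 0.10). Of 39 cell cycle and replication genes 10 rose and 1 fell (adjusted p = 8.82e-06; adjusted p = 0.303 with an estimated correlation). The replication factors Orc1 (1.63 ± 0.07) and Cdt1 (1.44 ± 0.10) were among those that rose, and cyclin D2 (Ccnd2) fell by 2.23.

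Hox genes fell, with 13 of 37 called lower (adjusted p = 1.21e-08; adjusted p = 0.229 with an estimated correlation), among them Hoxa5 (-2.09 ± 0.12) and Hoxd13 (-1.72 ± 0.09). Skeletal muscle genes fell, with 7 of 12 called lower and 1 higher (adjusted p = 0.00245; adjusted p = 0.303 with an estimated correlation). The MEF arrays held cardiac actin (Actc1) at a signal of 4881 ± 392, embryonic myosin (Myh3) at 588 ± 170 and myogenin (Myog) at 256 ± 10, and the respective iPS signals were 290 ± 66, 49.99 ± 1.4 and 51.5 ± 9.7. Genes of TGF-beta and BMP signalling fell, with 11 of 23 called lower and 1 higher (adjusted p = 7.44e-05; adjusted p = 0.293 with an estimated correlation), including Ltbp1 (-3.28 ± 0.14) and follistatin (Fst, -2.34 ± 0.19). In the Dlk1-Dio3 imprinted cluster 3 of 5 genes fell: Dlk1 (-3.35 ± 0.08), Rian (-1.69 ± 0.11) and Meg3 (-1.07 ± 0.13), the last not called without iPS replicate 2 (-0.96). This list was at the threshold (adjusted p = 0.0492; adjusted p = 0.293 with an estimated correlation) and was not called without MEF replicate 2 (0.0618), MEF replicate 3 (0.0530) or iPS replicate 3 (0.0547), nor with quantile normalization (0.0601), median centring (0.0568), dim genes left out (0.0762) or the replicate block (0.0518). Rtl1 (-0.08) and Dio3 (0.08) were not called.

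The remaining 13 lists did not pass. Of 34 other imprinted genes 5 were called higher and 10 lower, with Phlda2 higher (3.84 ± 0.09) and Igf2 lower (-3.34 ± 0.19). Wnt signalling had 2 of 21 genes higher and 9 lower, including Wnt5a (-3.04 ± 0.11). Ectoderm and neural genes had 5 of 19 higher and 3 lower, endoderm genes 1 of 21 higher and 4 lower, mesoderm genes 1 of 19 higher and trophoblast genes 2 of 13 in each direction. The p53 and CDK inhibitor list had 4 of 21 genes higher and 3 lower, and the interferon list 2 of 25 in each direction. Of 9 genes of the 2-cell stage 0 were called. Of 14 macrophage genes only Cd68 was called (1.12 ± 0.10), and of 12 endothelial genes Pecam1 was higher (1.81 ± 0.21) and Emcn lower (-1.04 ± 0.06), the latter not called without iPS replicate 3 (-0.98). Housekeeping genes had 1 of 11 called, Gusb (-1.51 ± 0.10). Among the sex-linked genes, Xist, the RNA of the inactive X chromosome, fell from 796 ± 70 to 80.8 ± 5.9, and Uty rose (2.55 ± 0.09). The sex of the MEF donors is not given, so a difference in sex is not excluded as part of either change. It would move Y-linked genes alike, but the Y-linked Eif2s3y (0.76 ± 0.07) and Kdm5d (-0.10 ± 0.09) were not called. A difference in sex alone thus does not account for the rise of Uty. For the endoderm list (median 0.03, mean -0.37) and the trophoblast list (0.01, 0.17) the camera direction was down, as for the macrophage list (-0.07, 0.01). The interferon list was called without R1 replicate 2 (adjusted p = 0.0470) and the Wnt list without MEF replicate 1 (0.0441). Removing the minimum difference raised the count of called genes to 9571 and turned its balance, with 4945 higher and 4626 lower, and testing against a difference of 1 lowered it to 1642.

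**Figure D1:**
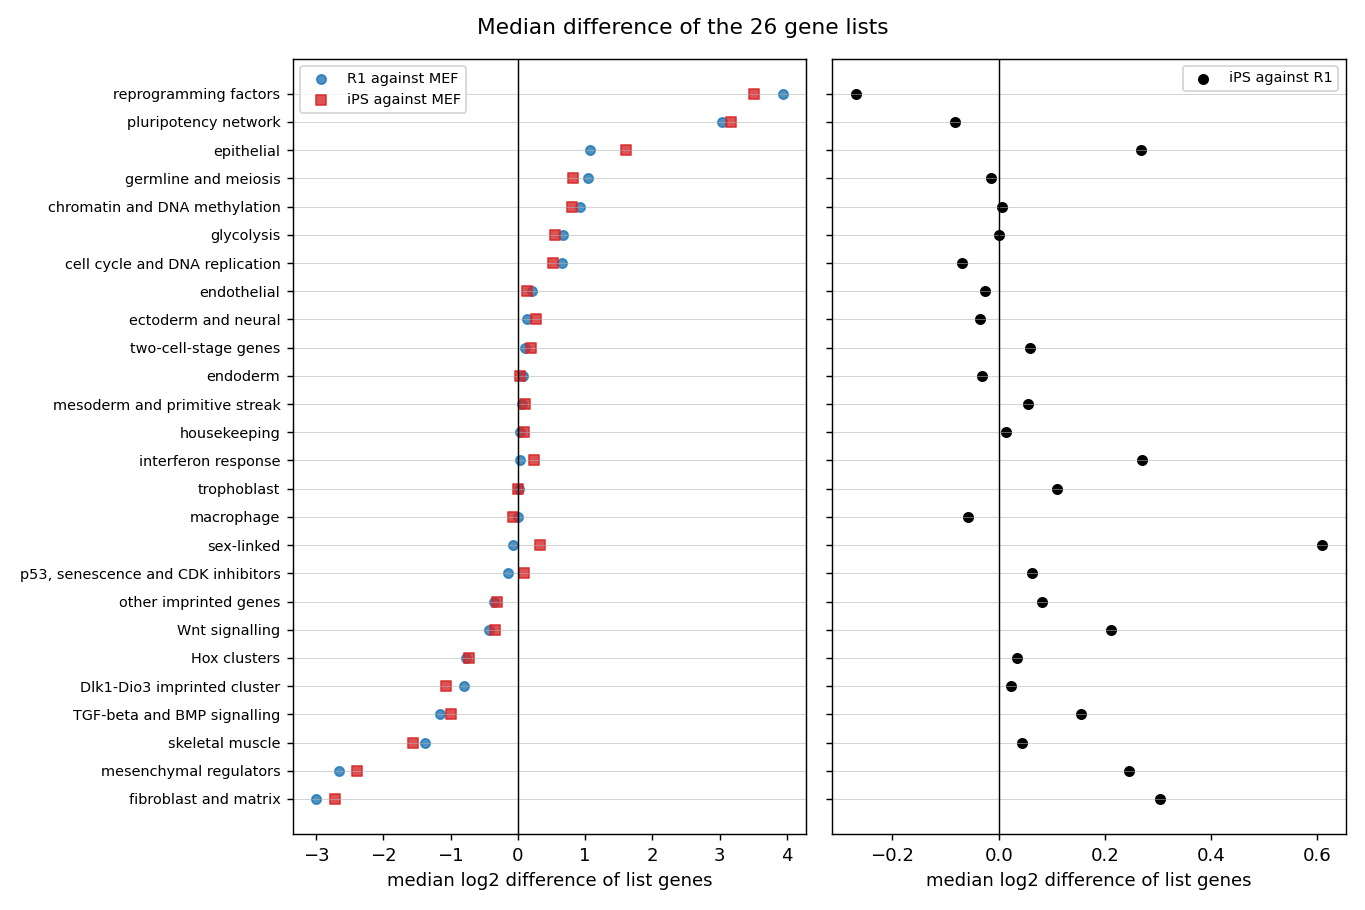
Median log2 difference over the measured genes of each of the 26 gene lists, for R1 and iPS against MEF (left) and iPS against R1 (right, on a scale of its own). The pluripotency network lies at 3.16 in iPS against MEF, the fibroblast and matrix list at -2.72, and in iPS against R1 the medians range from -0.27 to 0.61.

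The comparison of R1 cells with MEF gives the reference difference between an embryonic stem cell line and fibroblasts. The pluripotency network rose and fibroblast genes fell here as well, calls that were again lost with an estimated correlation (adjusted p = 0.229 and adjusted p = 0.255). Dppa5a rose by 6.96 ± 0.24, Nr0b1 by 6.72 ± 0.20, Tdgf1 by 6.71 ± 0.12, Zfp42, the Rex1 gene, by 6.16 ± 0.11 and Pou5f1 by 6.10 ± 0.09. Nanog rose by 5.68 ± 0.09, Sox2 by 5.50 ± 0.07 and Klf4 by 2.39 ± 0.06, while Myc, at -0.87 ± 0.12, was not called. Tgfb3 (-4.63 ± 0.17), Fbln5 (-4.62 ± 0.10), Ankrd1 (-4.53 ± 0.25) and the smooth-muscle gene Tagln (-4.53 ± 0.24) fell most. In all, 2689 genes were called, 1108 higher and 1581 lower in R1 cells, with fully separated arrays for all of them. Without a minimum difference the balance turned, with 5162 higher and 4586 lower of 9748. Zfp980 (6.32 ± 0.16) and Zfp640 (6.12 ± 0.17) were also among the largest increases. They belong to a family of near-identical zinc-finger genes, so which member was measured is uncertain.

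In R1 cells 42 of 45 pluripotency genes rose (adjusted p = 8.83e-21; adjusted p = 0.229 with an estimated correlation), as did 3 of the 4 reprogramming factors (adjusted p = 0.0200; adjusted p = 0.293 with an estimated correlation). Fibroblast and matrix genes fell, with 34 of 37 lower and 1 higher (adjusted p = 5.28e-18; adjusted p = 0.255 with an estimated correlation), including Postn (-4.46 ± 0.26). Mesenchymal regulators fell, with 22 of 24 lower (adjusted p = 1.27e-15; adjusted p = 0.247 with an estimated correlation). Epithelial genes rose, with 12 of 24 higher and 1 lower (adjusted p = 2.10e-06; adjusted p = 0.293 with an estimated correlation), Epcam by 4.59 ± 0.09. Germline genes rose, with 12 of 24 called (adjusted p = 5.00e-06; adjusted p = 0.255 with an estimated correlation), for example Sycp3, a protein of the meiotic chromosome axis (3.37 ± 0.15). Glycolysis rose, with 8 of 19 called (adjusted p = 4.44e-06; adjusted p = 0.293 with an estimated correlation), as did chromatin genes, with 13 of 33 higher and 2 lower (adjusted p = 5.00e-06; adjusted p = 0.247 with an estimated correlation). Cell cycle genes rose, with 10 of 39 higher and 1 lower (adjusted p = 2.47e-06; adjusted p = 0.293 with an estimated correlation).

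Hox genes fell, with 12 of 37 lower (adjusted p = 7.09e-09; adjusted p = 0.229 with an estimated correlation), and so did skeletal muscle genes, with 8 of 12 lower (adjusted p = 0.000299; adjusted p = 0.293 with an estimated correlation). TGF-beta and BMP genes fell, with 12 of 23 lower and 1 higher (adjusted p = 6.93e-05; adjusted p = 0.293 with an estimated correlation). Wnt genes fell, with 8 of 21 lower and 2 higher (adjusted p = 0.0228; adjusted p = 0.350 with an estimated correlation), including Fzd2 (-2.50 ± 0.13). The Dlk1-Dio3 list was again at the threshold, with 2 of 5 lower (adjusted p = 0.0492; adjusted p = 0.293 with an estimated correlation). It was not called without MEF replicate 2 (0.0614), MEF replicate 3 (0.0548) or R1 replicate 2 (0.0602), nor with the other normalizations, dim genes left out or the replicate block. The other 12 lists did not pass. Of other imprinted genes 6 of 34 were higher and 11 lower, and this list was called without R1 replicate 1 (adjusted p = 0.0499) or R1 replicate 2 (0.0470). Ectoderm genes had 3 of 19 higher and 4 lower, endoderm genes 1 of 21 and 4, trophoblast genes 2 of 13 and 3, the p53 and CDK inhibitor list 5 of 21 in each direction, and interferon genes 1 of 25 and 2. Cd68 of the macrophage list and Pecam1 of the endothelial list were higher, and Emcn and Gusb lower. Medians and means differed in sign for endoderm (0.08, -0.27), trophoblast (0.01, -0.03), p53 (-0.15, 0.04) and interferon genes (0.03, -0.002), with the camera direction up only for the last. The sex-linked list had 2 of 4 genes in each direction, with Xist at -3.10 ± 0.12 and the Y-linked Eif2s3y at 1.35 ± 0.07.

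Of the 2689 genes called in R1 against MEF, 2257 were called in the same direction in iPS against MEF, which is 83.9% (exact binomial 95% interval 82.5 to 85.3). The interval treats genes as independent, and leaving out 1 array at a time gave 82.18% to 85.35%, which passes both its ends. Of the 2257 genes, 871 were higher and 1386 lower in both, and 0 genes were called in opposite directions. Independent lists of these sizes would share 56.3 higher and 120 lower genes. The fold changes of both comparisons correlated with r = 0.969 across genes, against 0.5001 in simulations without effects. Their covariance was 0.585 against a simulated 0.0032. In 20 simulations without effects, the highest number of genes called in the same direction in both was 0. Noise alone hardly reaches the minimum difference of 1, so this 0 adds no support. The simulated correlation of 0.5001 follows from the shared MEF arrays. For genes that do differ from MEF, part of the overlap may still come from the shared MEF arrays, which were too few to split. A further 266 genes were called only in iPS against MEF and 432 only in R1 against MEF, and the difference between iPS and R1 cells was itself called for 46 of these genes. The median ratio of the iPS change to the R1 change was 0.93 over the genes called in R1 cells. These genes were chosen by their R1 change, which alone can lower the ratio. It therefore does not show that iPS cells changed less.

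**Figure D2:**
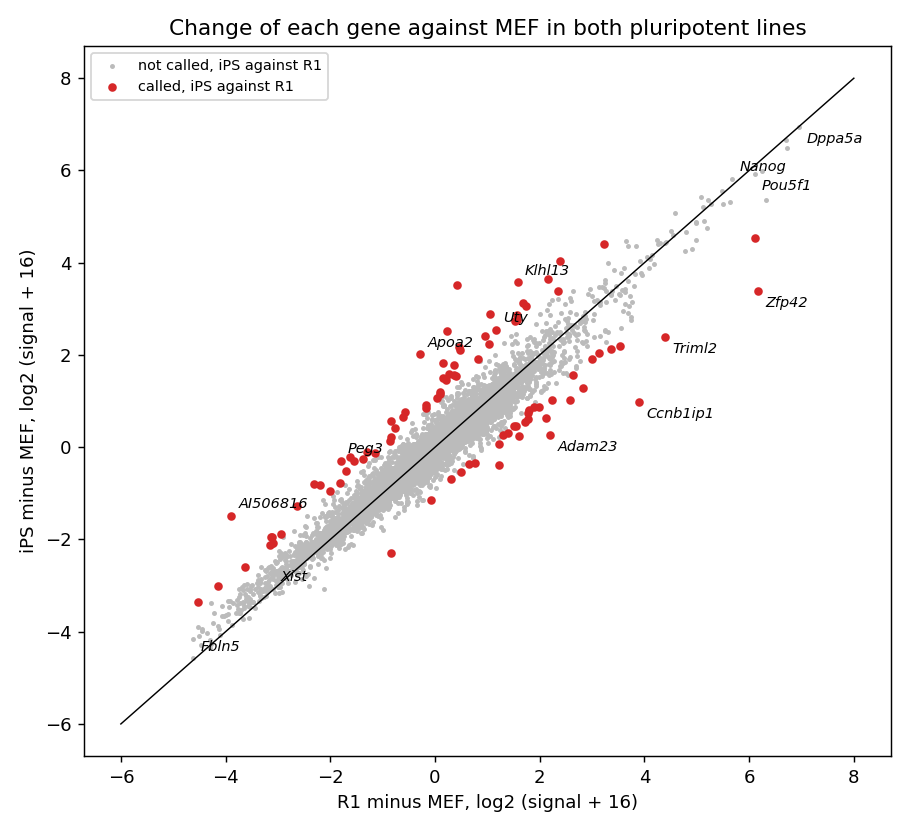
Log2 difference of each of 19938 genes in R1 against MEF (horizontal) and in iPS against MEF (vertical), with the line of equal change. The 92 genes called in iPS against R1 are red, with Zfp42, Triml2, Ccnb1ip1 and Adam23 below the line and Klhl13 and Apoa2 above it.

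The comparison of iPS with R1 cells sets the derived line beside the embryonic stem cell line. Zfp42, a zinc-finger gene used as a marker of undifferentiated stem cells, fell from 3539 ± 257 in R1 to 506 ± 55 in iPS arrays, a log2 difference of -2.77 ± 0.11, and its neighbour Triml2 fell by 1.999. Ccnb1ip1, which acts in meiotic crossing over, fell from 740 ± 31 to 84.9 ± 8.1 (-2.91 ± 0.08). Higher in iPS cells were the apolipoprotein gene Apoa2 (460 ± 37 against 81.03 ± 7.2; 2.30 ± 0.07), Klhl13 (1.998 ± 0.09), the iron exporter Slc40a1 (1.85 ± 0.20) and Dppa3, which encodes Stella, a maternal factor (1.63 ± 0.17). None of the 4 reprogramming factors was called: Pou5f1 lay at -0.19 ± 0.09, Sox2 at -0.23 ± 0.07 and Myc at -0.31 ± 0.12, while Klf4, at -0.63 ± 0.06 (adjusted p = 0.000299), missed only the minimum difference. Nanog lay at 0.14 ± 0.09. In all, 92 genes were called, 59 higher and 33 lower in iPS cells, all with fully separated arrays. Without iPS replicate 3 the split was 53 higher and 50 lower.

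By the rule, which passes over Riken symbols, the other largest increases were those of AI506816 (2.41 ± 0.14), Elobl (2.30 ± 0.30), Arl14epl (1.73 ± 0.14), the micro-RNA gene Mir302b (1.69 ± 0.29) and the autophagy receptor Calcoco2 (1.66 ± 0.19). The Riken gene 2210409E12Rik, named outside the rule, was higher by 3.098, more than any of them. The other largest decreases were those of Adam23 (-1.92 ± 0.10), securin (Pttg1, -1.60 ± 0.07), Zfp640 (-1.59 ± 0.17), Fmr1nb (-1.57 ± 0.06) and the phosphatase Inpp5d (-1.54 ± 0.13).

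Of 45 pluripotency genes only Zfp42 and Dppa3 were called, and the list did not pass (adjusted p = 0.321). Genes of the epithelial list rose, with 4 of 24 called (adjusted p = 2.21e-11; adjusted p = 0.247 with an estimated correlation). These were the claudin Cldn4 (1.33 ± 0.09), Esrp1 (1.17 ± 0.12), Rab25 (1.09 ± 0.15) and Cldn6 (1.02 ± 0.12). Rab25 was not called without R1 replicate 2 (0.99) or iPS replicate 3 (0.91), and Cldn6 not without R1 replicate 2 (0.90), iPS replicate 1 (0.96) or iPS replicate 3 (0.98). The epithelial list median lay between -0.20 and -0.15 on the R1 arrays and between 0.09 and 0.20 on the iPS arrays, relative to the mean of both groups.

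Fibroblast and matrix genes also rose, with 2 of 37 called (adjusted p = 2.26e-07; adjusted p = 0.383 with an estimated correlation), as did mesenchymal regulators, with 0 of 24 called (adjusted p = 4.32e-05; adjusted p = 0.338 with an estimated correlation). The fibroblast list median was -0.24, 0.09 and -0.30 on R1 replicates 1, 2 and 3 and 0.22, 0.08 and 0.13 on iPS replicates 1, 2 and 3, so R1 replicate 2 lay within the iPS range. Tagln rose (1.17 ± 0.24), but not without R1 replicate 1 (0.92), R1 replicate 3 (1.07) or iPS replicate 1 (1.07). Acta2, smooth-muscle actin, was called (1.15 ± 0.27, adjusted p = 0.0335), but lost the call without any 1 array other than R1 replicate 2, with differences of 0.86 to 1.20. Col1a1 (0.67 ± 0.15) and Thy1 (0.13 ± 0.12) were not called. The TGF-beta and BMP list rose, with 1 of 23 called, the connective tissue growth factor Ccn2 (1.18 ± 0.14; adjusted p of the list = 0.0136; adjusted p = 0.518 with an estimated correlation). This list was not called without R1 replicate 3 (0.165). Its medians were -0.06, 0.09 and -0.20 on R1 replicates 1, 2 and 3 and between 0.06 and 0.11 on iPS arrays, so R1 replicate 2 again lay within the iPS range. For the mesenchymal list they were -0.17, 0.05 and -0.19 on R1 arrays and between 0.07 and 0.16 on iPS arrays. Under fry the fibroblast (0.0968), mesenchymal (0.0750) and TGF-beta lists (0.150) were not called. Without R1 replicate 2 and iPS replicate 1, an alternative chosen after seeing the data, 96 genes were called in iPS against R1.

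**Figure D3:**
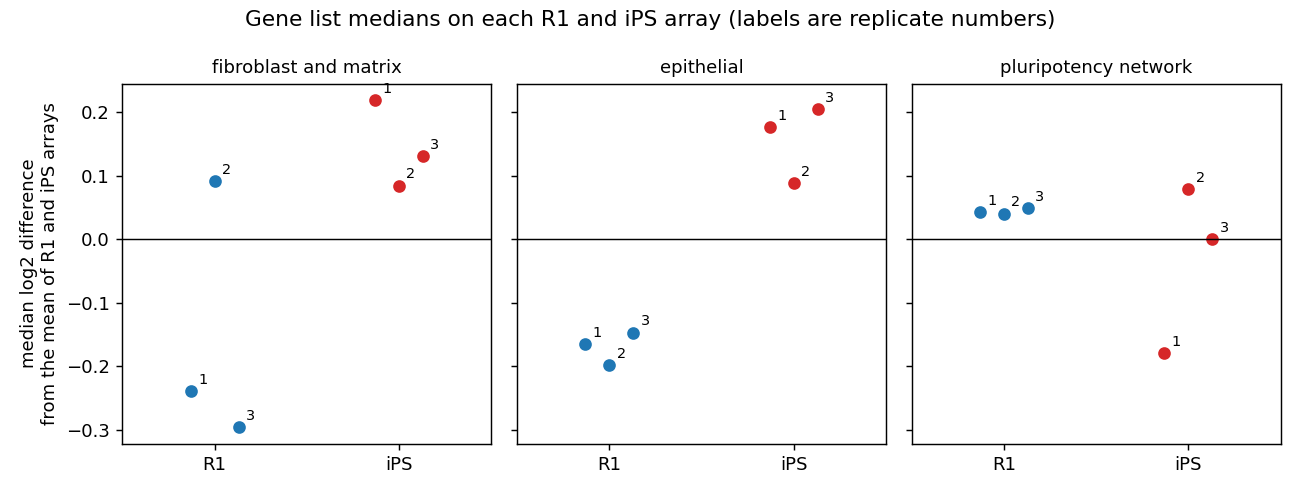
Median over the genes of 3 lists on each R1 and iPS array, as a log2 difference from the mean of the 6 arrays. R1 replicate 2 lies at 0.09 in the fibroblast and matrix list, within the iPS range of 0.08 to 0.22, and the epithelial medians of R1 and iPS arrays do not overlap.

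Other imprinted genes rose as a list, with 2 of 34 called higher and 1 lower (adjusted p = 0.00788; adjusted p = 0.248 with an estimated correlation). These were the paternally expressed Peg3 (1.51 ± 0.08), Sfmbt2 (1.44 ± 0.18) and Zdbf2 (-1.36 ± 0.15). Peg3 was measured at 1111 ± 52 in MEF, 307 ± 11 in R1 and 911 ± 111 in iPS arrays. In the Dlk1-Dio3 cluster 0 of 5 genes were called, with Meg3 at -0.27 ± 0.13, Rian at -0.49 ± 0.11 and Dlk1 at 0.13 ± 0.08. Its list median was 0.02 while the camera direction was down (adjusted p = 0.684). Of the sex-linked genes Uty (1.39 ± 0.09) and Kdm5d (1.19 ± 0.09) rose, while Eif2s3y lay at -0.59 ± 0.07 and Xist at 0.03 ± 0.12 (list adjusted p = 0.0717).

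Without any called member, the interferon list rose (adjusted p = 5.11e-05; adjusted p = 0.293 with an estimated correlation), with a median of 0.27. So did the Wnt list, with a median of 0.21 (adjusted p = 0.00497; adjusted p = 0.293 with an estimated correlation), and the trophoblast list, with a median of 0.11 (adjusted p = 0.00968; adjusted p = 0.304 with an estimated correlation), which was not called without iPS replicate 1 (0.0560). The interferon medians of the arrays resembled those of the fibroblast list, with R1 replicates 1, 2 and 3 at -0.20, 0.05 and -0.215 and iPS replicates between 0.04 and 0.13. The 4 reprogramming factors fell as a list, with a median of -0.27 (adjusted p = 0.00146; adjusted p = 0.248 with an estimated correlation).

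The other lists did not pass. Among their members, Sycp3 fell (-1.25 ± 0.15), the skeletal-muscle light chain Mylpf rose (1.21 ± 0.19) and Otx2, a transcription factor of the epiblast and brain, fell (-1.34 ± 0.26). Otx2 was not called without R1 replicate 1 (-1.19) or R1 replicate 3 (-1.22). Sox11 rose (1.03 ± 0.09), but not without iPS replicate 1 (0.99). Cubn, of the endoderm list, fell (-1.04 ± 0.16), but not without R1 replicate 3 (-0.81). Medians and means differed in sign for ectoderm (-0.03, 0.04; camera direction up) and chromatin genes (0.01, -0.06; down), and glycolysis genes had a median near 0 and a mean of -0.03 with the direction up. The sex-linked list was called without R1 replicate 2 (0.0374), the mesoderm list without R1 replicate 1 (0.0499) or iPS replicate 3 (0.0028), and the cell cycle list, with a median of -0.07, without R1 replicate 1 (0.0464), iPS replicate 2 (0.0137) or iPS replicate 3 (0.0065). Without a minimum difference 1698 genes were called, 821 higher and 877 lower, and with a test against a difference of 1 only 10, 4 higher and 6 lower, so in both the balance turned. With a pseudocount of 64 there were 31 higher and 14 lower, and with a pseudocount of 1 there were 71 and 51.

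**Figure D4:**
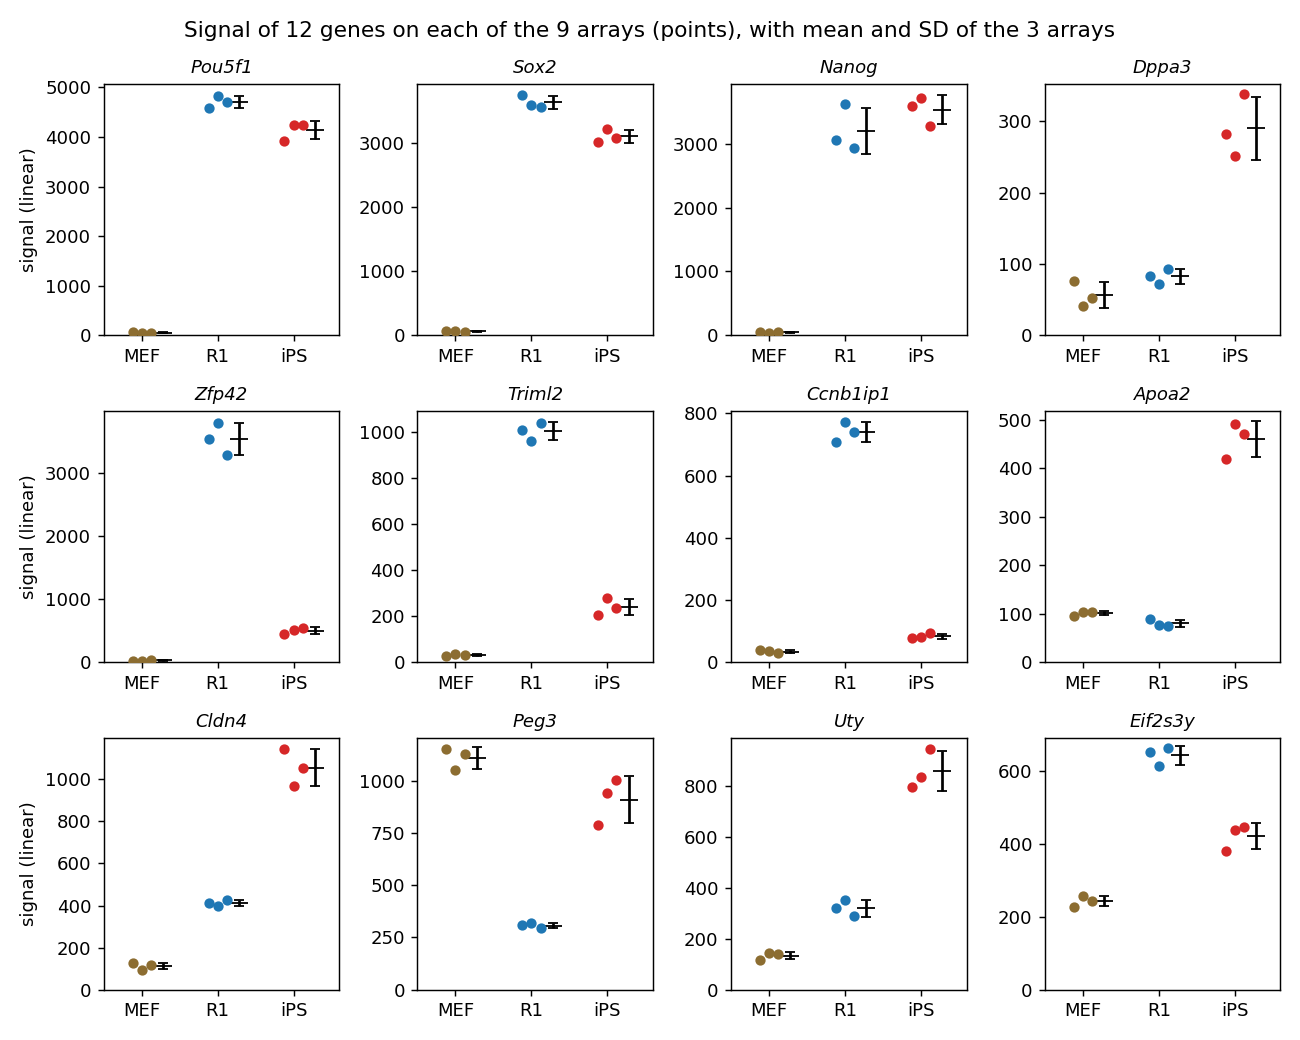
Linear signal of 12 genes on each array of MEF, R1 and iPS cells, with the mean and SD of 3 arrays beside the points. Zfp42 stood at 3539 in R1 and 506 in iPS arrays, and Eif2s3y (642 and 421) moved opposite to Uty (320 and 861).

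For the 92 genes called in iPS against R1, the place of the iPS mean relative to MEF was described. It lay between the R1 and MEF means for 47 genes, or 51.1% (95% interval 40.4 to 61.7), and for 43.0% without iPS replicate 1 and 55.7% without R1 replicate 2, the lowest and highest shares when an array was left out. Of these, 21 were higher and 26 lower in iPS cells, for example Peg3 and Zfp42. It lay beyond R1 on the side away from MEF for 31 genes, or 33.7% (24.2 to 44.3). Of these 29 were higher in iPS cells, among them Dppa3, Cldn4 and Klhl13, and 2 were lower. The MEF mean lay between the others for 14 genes, among them Apoa2. The planned simulation set R1 and iPS equal and kept MEF at its measured distance from R1. It gave 32.8% between R1 and MEF and 32.4% beyond R1. Its genes were picked by simulated noise from all genes tested, not from genes like the 92 called. These shares are therefore no chance value for the 92 genes. The places also depend on low MEF signals, as for Zfp42 (33.8 in MEF). A gene near background in MEF and higher in R1 lies almost always between them if lower in iPS cells. If higher in iPS cells, it lies beyond R1. For such genes the place does not show a tendency towards MEF.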

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

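The splits of the arrays were planned, and the tests of the fibroblast genes, of Zfp42 with Triml2 and of the Y-linked genes were chosen after the results were seen. With 10 splits of 6 arrays into 3 and 3, the share of splits that give as many genes cannot fall under 0.05. In iPS against MEF 2523 genes were called and 0 in the highest other split, in R1 against MEF 2689 and 0, and in iPS against R1 92 and 0. As many genes were given by 1 split in each case, the real one. Every other split mixes the arrays of both groups, which shrinks a real difference and raises the spread. Counts of 0 in those splits therefore add no support. Groups of 3 were not tested for outlying arrays.

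The changes of R1 and iPS cells against MEF differed, by the test of iPS against R1 itself, for 46 genes that were called in only 1 of these comparisons. Of the genes named by rule in iPS against R1, Elobl (2.30), Apoa2 (2.295), Arl14epl (1.73), Mir302b (1.69), Dppa3 (1.63), Mylpf (1.21) and Rab25 (1.09) were higher in iPS than in R1 cells and were called against MEF, as higher, in iPS cells only. Peg3 (1.51), Kdm5d (1.19) and Sox11 (1.03) were higher in iPS than in R1 cells and were called against MEF, as lower, in R1 cells only. Ccnb1ip1 (-2.91), Adam23 (-1.92), Pttg1 (-1.60) and Zdbf2 (-1.36) were lower in iPS than in R1 cells and were called against MEF, as higher, in R1 cells only. Some missed the minimum difference against MEF in the other line while moving the same way. These were Ccnb1ip1 (0.988) and Sox11 (-0.784) in iPS cells and Rab25 (0.822) in R1 cells. The uncalled differences of the other genes were smaller, and those of Apoa2 (-0.283) and Pttg1 (-0.385) went the opposite way. The difference between iPS and R1 cells was not called for Rab25 without R1 replicate 2 (0.99) or iPS replicate 3 (0.91), nor for Sox11 without iPS replicate 1 (0.99). Among 13768 probe sets without a single gene name, which the comparisons did not use, 34 were called in iPS against R1, 20 higher and 14 lower.

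The fibroblast list had a median of 0.30 in iPS against R1, with 2 of 37 genes called, and lost its call with an estimated correlation (adjusted p = 0.383) and with fry (adjusted p = 0.0968). Fibroblast RNA that varies between cultures of either line is a candidate explanation: the excess of R1 replicate 2 over the other R1 arrays correlated with the iPS minus R1 difference at r = 0.801 across 37 genes, which are not independent, and its list median lay in the iPS range. A larger share of cells with the MEF profile also remained possible. Of 30 abundant list genes 1, Fbln5, had an added signal whose 95% interval excluded the common median of 2.62% of the MEF signal. Among 88 genes of any kind with a MEF signal over 1000 and an R1 signal under 0.1 of it, 8 excluded theirs (binomial p = 0.0734). Both medians came from the tested genes, and many intervals were wide, as for Mmp2 (0.609%, SE 2.54) and Timp3 (3.59%, SE 3.7). The test could therefore hardly exclude a common share. The MEF, R1 and iPS signals of abundant Col1a1 were 10144, 785 and 1229; feeder cells were not measured, and incomplete silencing of fibroblast genes in iPS cells stays open as untested.

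Zfp42 and Triml2 were lower in iPS than in R1 arrays, and the next gene, Triml1, lay at -0.98 ± 0.14 (SE; not called, and named after its values were seen). Fewer pluripotent cells would lower the network as a whole, but its median without Zfp42 was -0.0679. Fewer copies of chromosome 8 would lower its other genes alike, but their median was -0.106. A sequence variant between the mice behind the lines cannot be told apart from lower expression, because all 3 genes had MEF signals under 60. A difference between derived and embryonic lines, which the design confounds with the line, may also account for it and was not tested.

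Uty and Kdm5d were higher and Eif2s3y was lower in iPS than in R1 arrays. A different share of cells with a Y chromosome would move all of them the same way, but Eif2s3y lay at -0.595 (adjusted p = 0.0011). Y chromosomes of different strains cannot be told apart from other causes. The MEF signal was nearer to iPS than to R1 for only 1 of Uty and Kdm5d. Nor is the sex of the MEF donors given in the sources used here, and the MEF arrays held both Xist (796) and the Y-linked Eif2s3y (242). Other differences between the lines stay open as untested.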

How the results depend on the processing

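The alternatives without a pseudocount and without R1 replicate 2 and iPS replicate 1 together were chosen after seeing the data. Total counts of genes stayed within 1.5 times their main values except under a changed threshold, with all probe sets or with a pseudocount of 64. Counts by direction moved further. A lower threshold raises counts by construction: without a minimum difference, 9571 (iPS against MEF; 4945 higher, 4626 lower), 9748 (R1 against MEF; 5162, 4586) and 1698 (iPS against R1; 821, 877) genes were called, and each balance turned. The overlap was then 87.8%; the cause of its rise and of the turned balances was not tested. A test against a difference of 1 gave 1642 for iPS against MEF (588 higher, 1054 lower), 677 higher for R1 against MEF and 10 for iPS against R1 (4 and 6). With more probe sets tested, those without a single gene name included, iPS against R1 gave 144 (93 and 51), and the higher genes against MEF were 1597 in iPS and 1722 in R1 cells. With a pseudocount of 64 iPS against R1 gave 45 (31 and 14), and the lower genes were 51 with a pseudocount of 1, 56 with none and 50 without iPS replicate 3, against 33. Without dim genes, array correlations were 0.820 (MEF with R1), 0.836 (MEF with iPS) and 0.985 (R1 with iPS). Leaving out 1 array at a time gave overlaps of 82.2% to 85.3% and 79 to 106 genes in iPS against R1. With an estimated correlation 0 list tests passed, against 36, and under fry 46 passed. Under fry, 2 lists in R1 against MEF passed with the direction turned from camera's, which had not called them: p53 and CDK inhibitors (median -0.149, fry up) and ectoderm (median 0.131, fry down); the cause was not tested. Replicate numbers did not pair the arrays throughout, as seen in each array's deviations from its group mean. Between same-numbered arrays of different groups, these deviations correlated at -0.082 to 0.245. For 4 of 9 arrays, the best correlated array of another group had the same number. All pairs of replicate 1 lay between 0.21 and 0.245, so an effect shared by these arrays was not excluded. With the number as a replicate block, 2523, 2689 and 92 genes were called, and 34 lists. Without R1 replicate 2 and iPS replicate 1 the counts were 2593, 2722 and 96, and without a pseudocount 2885, 3059 and 127. Of 247 named results, which include genes that were not called, 10 lost their call when some array was left out. Among those in iPS against R1 were Acta2, Tagln, Otx2, Rab25, Cldn6, Cubn and Sox11. With a call in either fit, 0 changed direction. Named genes were refitted in 12 alternatives, namely other normalizations, the replicate block and each array left out. They were not refitted with changed thresholds, pseudocounts or treatments of probe sets. Signals near background limit what dim genes show.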

Other observations

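The tests of neighbouring genes and of chromosomes 8 and X were chosen after the results were seen. Further genes called in iPS against R1 are named here outside the rule, picked after their values were seen, and no list of them was tested. Jun (1.38), Fosb (1.06), Ccn1 (1.05) and the gap-junction gene Gja1 (1.401) were higher in iPS cells, as were Wnt8a (1.32), the kinase gene Pim2 (1.22) and the interferon-induced Ifitm3 (1.14). The LIF receptor gene Lifr (-1.10), the FGF-pathway inhibitor Spry4 (-1.10) and the genes Stag3 (-1.09) and Sohlh2 (-1.20) were lower. Mir300 (-1.01) and Mir380 (-1.05), micro-RNA genes of the Dlk1-Dio3 region, were also lower.

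Within a distance of 3 tested genes, 6 pairs of genes were called in the same direction in iPS against R1, after 1 pair of micro-RNAs was left out. In 10000 permutations of the calls over all genes the mean was 0.667 and the highest number 6 (permutation p = 2e-04). Some of these pairs were known before the test: without Zfp42 with Triml2 and Kdm5d with Uty, and with calls permuted only over the 14368 genes with a mean signal of at least 50 in some group, 4 pairs stood against a mean of 0.743 and a highest number of 5 (permutation p = 0.0061). The pairs were Zfp42 with Triml2, Zdbf2 with Adam23, Elobl with 2210409E12Rik, Rcbtb2 with Lpar6, Hmgn5 with Sh3bgrl and Kdm5d with Uty. One hypothesis is that differences between iPS and R1 cells act on stretches of neighbouring genes; what sets such stretches apart was not tested.

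Genes on chromosome 8 with a mean log2 value over 8 were slightly lower in iPS than in R1 arrays, with a median difference of -0.106 over 347 genes, of which 72.6% were lower, against -0.0159 over all 6241 such genes. The permutation p was 2e-04, the smallest that 10000 permutations give for a two-sided test, before any correction for 20 chromosomes. The chromosome's list median lay between 0.05 and 0.07 on R1 arrays and between -0.11 and -0.02 on iPS arrays. When its genes were parted at their median start position, the part with the smaller shift had a median of -0.0834. That some R1 cells carry an extra chromosome 8 is a candidate explanation. Against MEF the chromosome's median was 0.187 in R1 and 0.1 in iPS cells, both within the range of the other chromosomes (-0.026 to 0.198 and 0.0162 to 0.221), so fewer copies in some iPS cells were not excluded. Chromosome X moved the other way by a similar amount, with a median of 0.0859 over 195 genes, arrays at -0.063 to -0.0229 in R1 and 0.00466 to 0.0836 in iPS cells, and the same permutation p of 2e-04; an extra chromosome 8 does not account for it.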
